A study of Oryza sativa Japonica Group and Oryza sativa Indica Group with 129 samples.

How the data were processed

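Gene expression was measured in rice leaf blades on 129 one-colour (Cy3) oligonucleotide microarrays. Per the labels, the uppermost fully expanded leaf of the main stem was sampled about weekly in paddy fields, late in the morning, and total RNA was extracted with a silica column kit and labelled by linear amplification. The cultivars were Nipponbare and Koshihikari, whose organism label is the japonica group, and Takanari and IR64, whose organism label is the indica group. The fields held soil of low (LP) or high (HP) available phosphate. There were 13 series of arrays, each of 1 cultivar in 1 soil in 1 year, and each cultivar, soil, year and day had 1 array, so no day was replicated within a series.

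The authors deposited 2 kinds of values. The scanner files hold fluorescence intensity in arbitrary units (background-corrected processed signal, mean signal and local background) with quality marks for each spot, extracted per the file headers with Feature Extraction 10.5.1.1 for 10 arrays (Nipponbare LP 2012) and 11.5.1.1 for 119 arrays; the labels state the latter version for every array. The deposited value table holds log2 values, which the authors obtained by subtracting from the log2 processed signal the 75th percentile of each array over all spots, controls included. The deposited value minus the log2 processed signal was constant within each array, to a range of 9.92e-08, so the table is not centred by gene. This does not test which percentile or which spots were used. Column medians of the deposited table lay between -3.25 and -2.64.

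Of 45151 spots per array, 43734 were not controls, and 42105 of those carried a locus ID of the rice annotation in the array's own description, for 29689 loci. The files give no genome coordinates, and the chromosome of a gene is the number after Os in its ID. The log2 processed signal minus the 75th percentile over non-control spots of the array was used. Spots marked as outliers (23 to 141 per array) were left out and replicate spots were averaged. Of several probes for a gene, the one with the highest mean over the 129 arrays was used; 268 probe sequences are given for more than 1 locus, so such loci share a value. A gene was tested where its probe was well above background, by the mark in the files, on at least 25% of the arrays of the comparison. The 75th percentile of the signal lay between 640 and 3464 units, no spot was saturated, and 66.7% to 83.2% of spots were well above background. This percentile differed along the compared factors. In Nipponbare LP 2015 it was 1054, 1286 and 1383 at 14, 22 and 28 DAT (days after transplanting), and 2485, 2579 and 2673 at 62, 69 and 76 DAT. Its series medians in 2016 were 1178 to 1344 in indica and 1620 to 1739 in japonica. Whether array brightness moved the counts was not tested. The number of arrays limits the precision. The probes follow the japonica sequence.

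All tests across genes used limma 3.58.1 in R 4.3.3 with Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p under 0.05, 2-sided. Errors of log2 differences are the moderated standard errors (SE) of limma unless SD is written. For soil phosphate, each of 6 pairs of an LP and an HP series (Nipponbare 2014, 2015 and 2016, and Koshihikari, Takanari and IR64 2016) gave 1 value per gene, the mean of LP minus HP over matched sampling rounds. For growth stage, each of 7 cultivar-years gave late (60 days after transplanting, DAT, or later) minus early (30 DAT or earlier). LP and HP series were averaged where both existed, and Nipponbare 2012 had LP alone. Subspecies and cultivars were compared on the means of the 8 series of 2016 with soil as a term, so these p-values measure the spread between LP and HP series of a cultivar and not the spread among cultivars of a subspecies. Years were compared by an F test on 6 Nipponbare series. The change of the soil difference from early to late, and its difference between subspecies, were tested as such.

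Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the 26 lists with at least 3 measured members. Members past the threshold were counted among all genes and adjusted over the list alone. Some lists were given by locus ID and others by wording in the gene description, and lists overlap, since SPX domain proteins, purple acid phosphatases and glycerophosphodiester phosphodiesterases also stand in the phosphate lists. Before any value was looked at, OsHAD1 and Osl2 were dropped because their descriptions name another protein family; OsIPS2 and Ghd7 have no probe. Lists of TIFY proteins and SWEET transporters had 0 members by their wording, and a list of root and seed markers had too few measured members, so these were not tested. The disease resistance wording also takes in a family of disease resistance response proteins, and the heat shock wording takes in DnaJ proteins. Gene symbols follow the lists.

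The comparisons, the lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule took, for each main comparison, the 8 largest rises and the 8 largest falls among called genes with the same sign in every unit, a probe well above background on all arrays of at least 1 group and a description that names a protein, and 3 of each for the other comparisons. It also allowed up to 4 members of each list with a called member. Which of those list members are named was decided after their values were seen, and 1 gene that the rule takes is not reported here. Genes named for the early window of the soil comparison were those named by the rule or members of the fixed lists, and the early window as a comparison of its own was added after the data were seen. A fold is given only where both groups were measured above background; where 1 group had no spot above background on any array, a bound against the lowest signal above background is given as "at least".

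Alternatives were normexp background correction (offset 50), quantile normalization, the deposited table, the mean of the probes of a gene, no filter and a 75% filter, other units and blocks, and leaving out each unit. Added after seeing the data were the pair scanned in 1 batch, early, middle and late windows, slide terms, comparisons within slides, splits by year or cultivar, soils taken alone, and list counts in the early window and with normexp. The 129 arrays lay on 35 slides and were scanned in 8 batches by the scan times in the file headers. LP and HP were scanned in different batches in 2014 and 2016 and in 1 batch in 2015, so the 2015 pair is given beside pooled soil values. In that pair the early LP and early HP arrays lay on different slides. No slide held both subspecies, years lay on different slides, and 5 slides held early and late arrays, which came from different series on each slide.

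The tests were checked on simulated data, drawn with the spreads between arrays and between series seen here and with known changes added. Of 66 genes shifted by 2 on the log2 scale, 63 were recovered in the soil design, 66 in the growth stage design, 60 in the subspecies design, 44 and 36 between cultivars, 55 for soil by stage and 48 in 1 sampling round. The designs for year and for soil by subspecies recovered 0 of 66. Of 67 genes shifted by 0.5, 24 were recovered for soil, 38 for growth stage and 0 for subspecies. In the data, 44 of 1335 soil calls and 5370 of 16817 subspecies calls were more than 2-fold, so recovery at a shift of 2 does not describe most calls. A list of 224 genes shifted by 0.3 was called and the other lists were not. Genes and series were drawn independently, so this check leaves out correlation among genes of a list and among series of the same year. A spread of the early to late change among cultivar-years was not simulated, so the recovery for growth stage and soil by stage leaves that spread out. Only 200 of 22614 genes were changed in each simulation. Data were read with arrow 21.0.0, the data.table package (1.17.8) and pandas 2.3.3 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.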

Results

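The arrays followed rice leaves through the season in 13 field series, 12 of them with 10 arrays and Nipponbare HP 2015 with 9. Nipponbare was sampled in LP soil in 2012 and in LP and HP soil in 2014, 2015 and 2016. Koshihikari, Takanari and IR64 were sampled in both soils in 2016. Sampling ran from 12 to 84 DAT. Between 66.7% and 83.2% of the spots of an array were well above background. Each day of a series is a single array, so errors come from the spread among pairs of series, cultivar-years or series.

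The LP and HP fields show which leaf transcripts differed between these fields and when, soil phosphate and field being the same factor. In the early window (30 DAT or earlier) the following genes of the phosphate starvation response were much higher in LP leaves in all 6 pairs. OsIPS1, a noncoding RNA that sequesters microRNA399 when phosphate is short, was higher by 8.05 ± 0.30 (log2, SE, n = 6 pairs), and OsMGD2, a galactolipid synthase, by 9.07 ± 0.48. OsIPS1 was well above background on 18 of 18 early LP arrays and 3 of 18 early HP arrays, and OsMGD2 on 5 of 18 HP arrays, so no fold is given for them. Os02g0325600, described as a phosphate starvation regulator, was 32.9-fold higher (5.04 ± 0.17), the glycerophosphodiester phosphodiesterase OsGDPD2 25.4-fold (4.67 ± 0.19) and OsSPX1, whose protein family senses phosphate status, 8.27-fold (3.05 ± 0.17). Late in the season (60 DAT or later) the LP minus HP differences were 0.24 ± 0.32 for OsIPS1, -0.02 ± 0.30 for OsMGD2, -0.09 ± 0.13 for Os02g0325600, 0.05 ± 0.17 for OsGDPD2 and -0.07 ± 0.11 for OsSPX1, and none was called.

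Of the phosphate sensing and signalling list, 6 of 13 measured members were higher and 2 lower in LP in the early window, also adjusted over the list alone. OsSPX3 differed by 5.03 ± 0.37 (well above background on 1 of 18 HP arrays), OsSPX2 was 6.29-fold higher and OsSPX6 stood at 1.86 ± 0.19. OsSPX-MFS1, a vacuolar phosphate transporter, was lower, at -1.54 ± 0.10, and the phosphate exporter OsPHO1;1 at -0.53 ± 0.12. Of the list for phosphate scavenging, lipid remodelling and uptake, 9 of 15 members were higher and 0 lower, or 12 and 0 adjusted over the list alone. They included the sulfolipid genes OsSQD1 (3.68-fold) and OsSQD2.1 (6.73-fold), the acid phosphatase OsPAP10a (4.57-fold), the phytase-type OsPAP23 (12.5-fold) and the phosphatase OsACP1 (7.95-fold). Outside these lists, digalactosyldiacylglycerol synthase 1 (Os04g0416900) was 7.41-fold and a phosphoenolpyruvate carboxylase kinase (Os04g0517500) 8.74-fold higher. By wording, 5 of 9 purple acid phosphatases and 5 of 9 glycerophosphodiester phosphodiesterases were higher and 0 lower, among them Os08g0535700 (37.2-fold) and Os04g0394100 (24.1-fold). SPX domain proteins had 5 higher and 1 lower of 8, and these last 3 counts were the same adjusted over the list alone. Cytosolic ribosomal proteins had 1 higher and 30 lower of 235, or 1 and 125 adjusted over the list alone, with a median of -0.29. The cyclin CycB1;1 stood at -1.45 ± 0.23 and the cell cycle kinase CDKB2;1 at -0.74 ± 0.09, the 2 called of 4 markers of meristem and dividing cells, of which 0 were called with normexp.

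**Figure D1:**
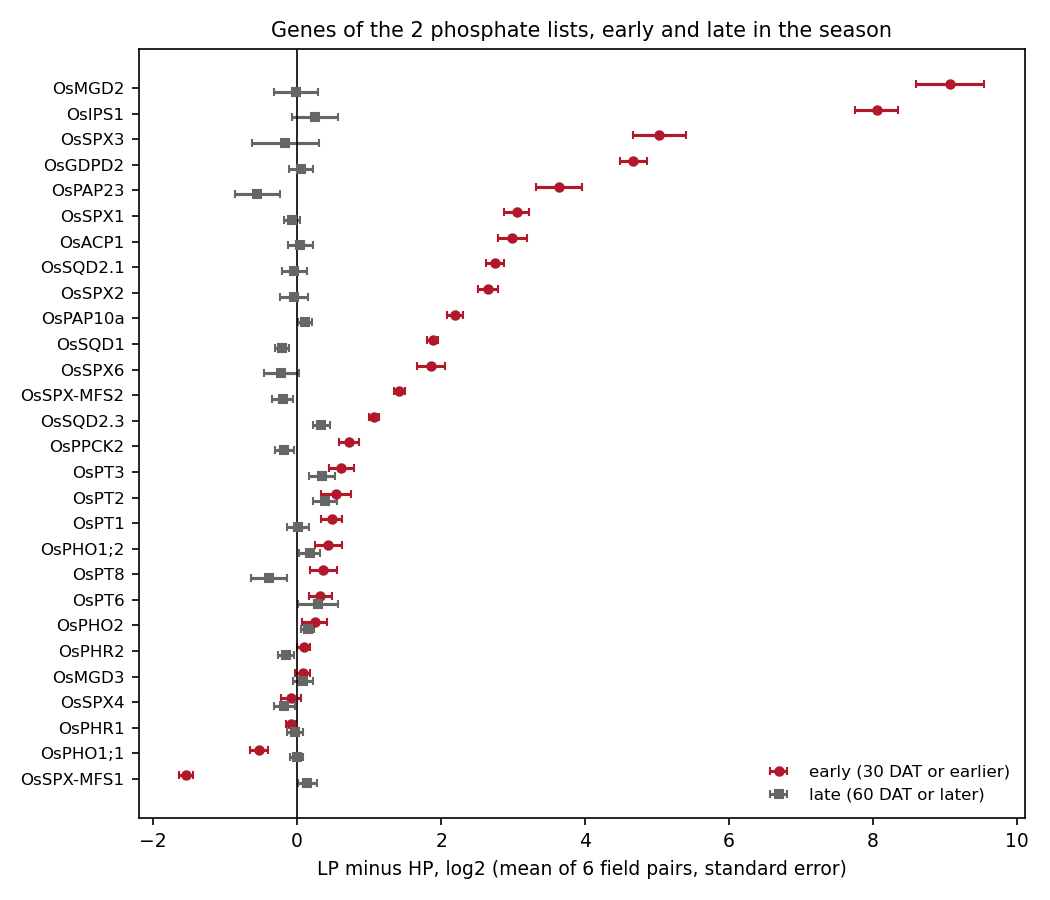
LP minus HP differences (log2, mean and SE of 6 pairs) early and late in the season for 28 genes of the phosphate lists. The early differences reach 9.07 for OsMGD2 and 8.05 for OsIPS1, while the late difference of both lies within 0.30 of 0.

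In the early window limma called 2150 of 23195 genes, 1046 higher and 1104 lower in LP (1078 and 835 with normexp), and 330 of them differed more than 2-fold. In the Nipponbare 2015 pair, whose soils were scanned in 1 batch, the early differences were 8.56 for OsIPS1 (SD 1.16, n = 3 rounds), 10.37 for OsMGD2 (SD 0.08), 4.20 for OsGDPD2 (SD 0.81), 5.25 for Os02g0325600 (SD 1.2) and 3.04 for OsSPX1 (SD 0.41). Of 1033 genes called in the early window without that pair, 934 (90.4%) had the same sign in it, against 65.6% of all genes. The early count fell to 1033 without Nipponbare 2015, 1192 without Nipponbare 2016, 496 without Koshihikari, 1361 without Takanari and 858 without IR64, to 33 with the 3 Nipponbare pairs alone, to 566 with the 4 pairs of 2016 alone and to 3 in the 2015 pair alone (1278 at an unadjusted p under 0.05). Soil and field are the same factor, and in 2014 and 2016 also soil and scan batch. Early LP and early HP arrays of the 2015 pair lay on different slides.

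Whether the soil difference itself changed through the season was tested directly, and LP minus HP went down from early to late in 171 genes and up in 27 of 23218. The late difference minus the early one was -7.67 ± 0.43 for OsIPS1, -8.95 ± 0.56 for OsMGD2, -5.08 ± 0.25 for Os02g0325600, -4.60 ± 0.31 for OsGDPD2, -3.18 ± 0.19 for Os04g0517500 and -3.12 ± 0.15 for OsSPX1 (n = 6 pairs each). This test used all arrays of each window, with the unmatched last LP array of Nipponbare 2015, so its values differ slightly from the differences above. Upward changes included an epoxide hydrolase (Os05g0542200, 1.90 ± 0.15), a diacylglycerol kinase (Os03g0425300, 0.94 ± 0.14), a flavin monooxygenase (Os04g0223500, 0.94 ± 0.14) and CycB1;1 (2.05 ± 0.19). Downward changes were called in 7 of 14 sensing members, 7 of 15 scavenging members, 5 of 9 SPX proteins, 2 of 9 purple acid phosphatases and 3 of 9 glycerophosphodiester phosphodiesterases, or 7, 10, 6, 5 and 5 adjusted over the list alone. With an estimated correlation in camera the adjusted p was 0.0066 for scavenging and 0.0379 for the phosphodiesterases, and 0.0536 for sensing, 0.051 for SPX and 0.102 for the phosphatases. The count of 198 genes was 104 without Nipponbare 2015, 110 without Nipponbare 2016, 103 without Koshihikari and 92 without IR64.

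By sampling round, 135 genes were called at 12 to 14 DAT, 201 at 19 to 22 DAT and 212 at 26 to 28 DAT, and 106, 148 and 148 of these were higher in LP. The next rounds gave 7, 0, 1, 1, 0, 0 and 0 genes, with 1608 to 3424 genes at an unadjusted p under 0.05 in each. The mean score of the 13 measured sensing genes, averaged over the season, was higher in LP in all 6 pairs, by 0.53 (SD 0.09, exact 2-sided sign-flip p = 0.0312, the smallest that 6 pairs allow). Within pairs the difference over rounds was 0.61 in Nipponbare 2014 (8 of 10 rounds, exact p = 0.00781, adjusted p = 0.0469), a call lost with normexp (0.31, adjusted exact p = 0.164) and after quantile normalization (0.52, 0.105). It was 0.63 in Nipponbare 2015, 0.50 in Nipponbare 2016, 0.58 in Koshihikari, 0.41 in Takanari and 0.44 in IR64, with adjusted exact p from 0.141 to 0.146. Successive rounds of a field are not independent, and 4 of the 6 pairs share the year 2016, so these p-values describe the series at hand.

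**Figure D2:**
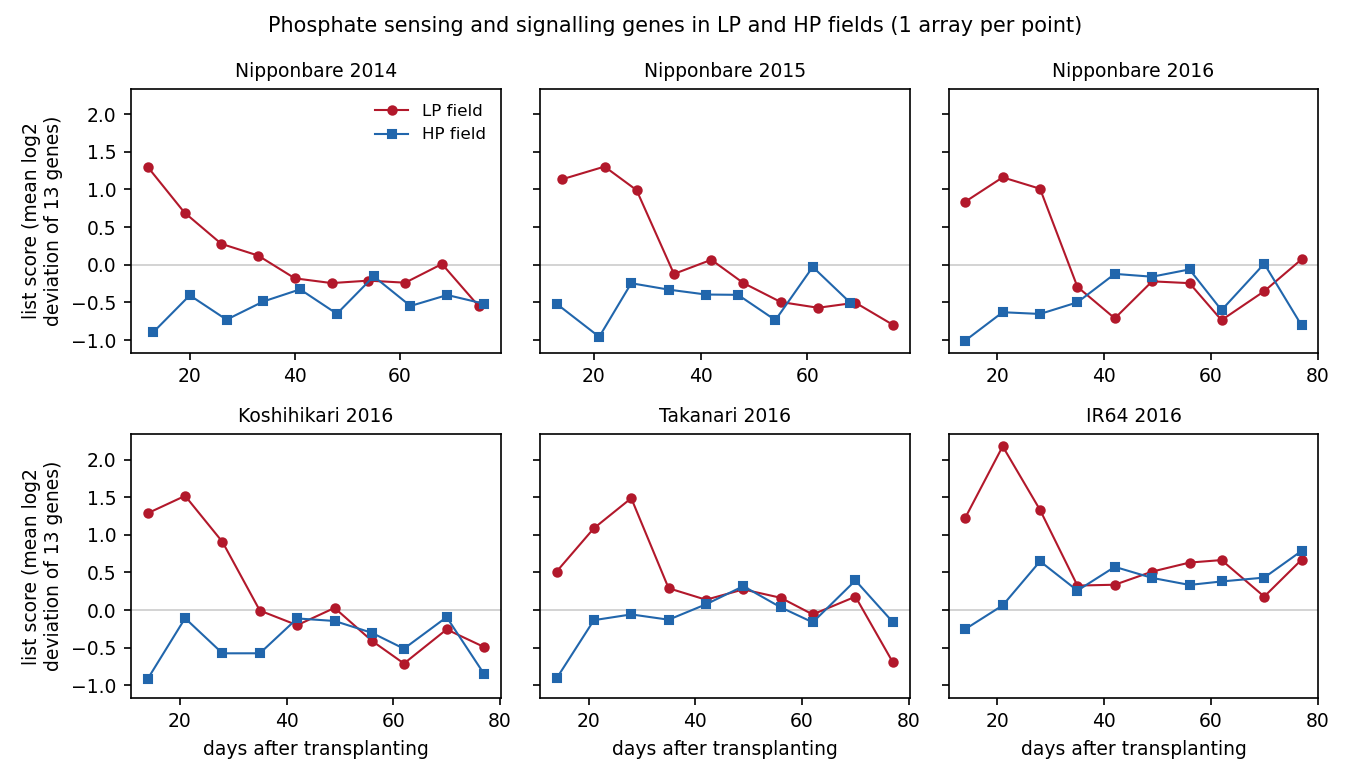
Score of the phosphate sensing list (mean of 13 genes, log2 against the mean of all arrays) by days after transplanting in LP (red) and HP (blue) leaves of 6 cultivar-years, with 1 array per point. Averaged over the season, LP exceeds HP by 0.41 in Takanari up to 0.63 in Nipponbare 2015.

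**Figure D3:**
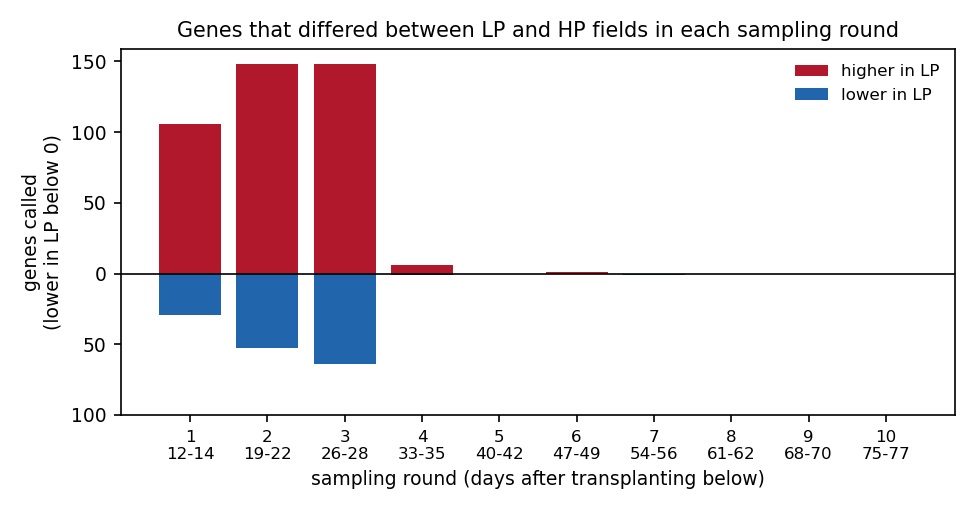
Number of genes called between LP and HP leaves in each sampling round, those higher in LP drawn upward and those lower downward (6 pairs, 5 in the last round). The first 3 rounds hold 135, 201 and 212 genes and no later round more than 7.

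Averaged over all rounds, the largest rises in LP of genes the rule names were Os02g0325600 (3.91-fold, 1.97 ± 0.14), an Hsp70 family gene (Os06g0212900, 1.19 ± 0.11), digalactosyldiacylglycerol synthase 1 (1.13 ± 0.06), a protein kinase (Os10g0100500, 1.11 ± 0.07), OsSPX1 (2.15-fold, SE 0.09), phosphoenolpyruvate carboxylase kinase (1.08 ± 0.18), a WD40 protein (Os05g0169200, 2.0-fold, SE 0.06) and OsSQD2.1 (0.95 ± 0.07). The largest falls were a DnaJ protein (Os04g0675400, -1.04 ± 0.17), a chloroplast cysteine synthase (Os01g0814800, -0.97 ± 0.08), a cytochrome P450 (Os01g0628900, -0.89 ± 0.16), a metallothionein (Os05g0202800, -0.89 ± 0.10), an amidotransferase (Os04g0643200, -0.82 ± 0.09), an F-box protein (Os07g0229200, -0.78 ± 0.16), WD-repeat protein 5 (Os03g0725400, -0.75 ± 0.08) and a TPR protein (Os08g0191900, -0.71 ± 0.07). Of the scavenging list 9 of 15 members were higher and 0 lower, also adjusted over the list alone (camera adjusted p = 5.19e-12, and 0.0349 with an estimated correlation). Of the sensing list 5 were higher and 1 lower of 13, or 7 and 2 adjusted over the list alone (adjusted p = 0.0352, and 0.188 with an estimated correlation). SPX proteins had 3 higher and 1 lower of 8, purple acid phosphatases 3 higher of 9 and glycerophosphodiester phosphodiesterases 4 higher of 9, each with an adjusted p of 0.181 with an estimated correlation. Adjusted over the list alone these lists had 6 higher and 1 lower, 5 higher and 6 higher.

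Among the other lists, 1 of 21 nuclear photosynthesis genes was higher in LP (RBCS4, 0.40 ± 0.09), or 18 adjusted over the list alone, with a median of 0.32 that was 0.10 after quantile normalization, where 0 members were called (0.33 against 0.23 for other genes of like signal, as means of the medians of 6 pairs). The camera adjusted p was 9.11e-10, and 0.265 with an estimated correlation. Light harvesting and photosystem proteins had 3 higher and 3 lower of 44 (25 and 3 adjusted over the list alone), for example the chlorophyll a-b binding gene Os01g0720500 at 0.67 ± 0.12, and cytosolic ribosomal proteins 0 higher and 17 lower of 235 (1 and 48). Among senescence genes RCCR1, of chlorophyll breakdown, stood at -0.48 ± 0.09 but at 0.026 with normexp. The sucrose synthesis gene OsSPS1 (0.69 ± 0.15), the diterpenoid gene CYP99A3 (0.42 ± 0.07) and the clock gene OsLHY (0.31 ± 0.05) were higher, and OsFKF1 of the clock list was lower (-0.67 ± 0.12). Peroxidases had 3 higher of 57, expansins 2 of 25 (OsEXPA13, 0.63 ± 0.10), glutaredoxins 1 of 27, heat shock proteins 3 higher and 4 lower of 115, glutathione S-transferases 1 and 1 of 51, WRKY factors 2 lower of 60 and histones 2 lower of 48. OsLHY (0.24) and OsEXPA13 (0.57) were not called after quantile normalization, nor was the F-box gene Os07g0229200 (-0.27) with normexp. Disease resistance proteins had 2 higher and 12 lower of 206, which turned to 6 and 3 with normexp. Over all genes 466 of 23195 were higher and 869 lower in LP. In the lists for nitrogen, iron, flowering time, abscisic acid and jasmonate, meristem and dividing cells, and floral organs, 0 members were called. Adjusted over the list alone, senescence had 4 lower, sucrose and starch 3 higher, defence 3 higher and 3 lower, nitrogen 2 and 2, iron 1 and 1, peroxidases 4 higher, expansins 3 higher, heat shock proteins 4 and 7, WRKY factors 1 lower and disease resistance 4 and 12, and the other lists of this paragraph the same as above. At the preset correlation 13 lists were called in camera, and 1, scavenging, with an estimated correlation, where the next smallest adjusted p was 0.181. Median and mean differ in sign for histones and glutaredoxins, and the direction of camera differs from the median for flowering time, defence, heat shock proteins, glutathione S-transferases and glutaredoxins, none of them called.

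Over all rounds limma called 1335 of 23195 genes, 466 higher and 869 lower in LP, 44 of them more than 2-fold, but 1023 higher and 564 lower with normexp. In the 2015 pair, of 1 scan batch, the all-round differences were 2.55 for Os02g0325600, 1.40 for OsSPX1, -1.16 for the DnaJ gene Os04g0675400 and -1.04 for the cysteine synthase. The count was 107 without IR64, 138 without Koshihikari, 172 without Takanari, 514 without Nipponbare 2015, 571 without Nipponbare 2016 and 2336 without Nipponbare 2014. It was 0 in the 3 Nipponbare pairs alone (1453 at an unadjusted p under 0.05), within the 2015 pair (3014), and in the middle (3606) and late (3381) windows. Whether the soil difference depended on the subspecies was tested on the 4 pairs of 2016, where limma called 0 of 23424 genes (2614 at an unadjusted p under 0.05), in a design that recovered 0 of 66 simulated 4-fold changes.

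Early and late leaves of the same series show how leaf transcripts changed through the season, in which plant age, date and weather change together. In the flowering list 8 of 13 members rose and 3 fell, or 6 and 4 with normexp, where the median of 0.89 went to 0.0080 (camera adjusted p = 0.0812, and 0.401 with an estimated correlation). The MADS-box gene OsMADS14, which acts in the floral transition, rose 294-fold (8.20 ± 0.26, SE, n = 7 cultivar-years), while Ehd1, a regulator of flowering time, was at least 4.05-fold higher, being above background on 0 of 38 early and 38 of 39 late arrays. A gene described as MOTHER of FT and TF1 (Os06g0498800) rose by 8.85 ± 0.23 and was above background on 1 of 38 early arrays, so its size depends on values near background. Cytosolic ribosomal protein genes rose in 197 of 234 members and fell in 10 (camera adjusted p = 1.53e-15, and 0.401 with an estimated correlation).

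Other large rises were an FKBP12 immunophilin (Os04g0352400, 6.61 ± 0.29), the metallothionein Os05g0202800 (67.0-fold, 6.07 ± 0.45), a protein kinase (Os09g0359500, 5.98 ± 0.86) and the PEBP family genes Os01g0748800 (5.94 ± 0.43) and Os01g0218500 (5.92 ± 0.18). The largest falls were a serine carboxypeptidase (Os03g0386800, -7.42 ± 0.20), a clathrin adaptor (Os11g0244600, -7.31 ± 0.24), a T2 ribonuclease (Os09g0537700, -7.11 ± 0.65), a glutaredoxin (Os01g0368900, -6.48 ± 0.52), a protein kinase (Os11g0113700, -6.22 ± 0.35), an aspartokinase and homoserine dehydrogenase of amino acid synthesis (Os09g0294000, -6.08 ± 0.31) and a gene described as FLOWERING LOCUS T protein (Os04g0488400, -5.99 ± 0.47). A plasma membrane proton pump (Os02g0797300) was at least 23.5-fold lower late. Each of these largest changes had 1 direction in 7 of 7 cultivar-years, with adjusted p from 4.19e-07 to 4.34e-04. The serine carboxypeptidase and the clathrin adaptor were well above background on 11 and 9 of 39 late arrays, and the kinase Os11g0113700 and Os04g0488400 on 21 and 22. Os01g0748800, Os01g0218500, FKBP12 and the kinase Os09g0359500 were so on 1, 5, 15 and 16 of 38 early arrays, and the size of these 8 changes depends on values near background. With series and slide as terms the metallothionein stood at 1.36 ± 2.25, the kinase Os09g0359500 at 0.76 ± 0.84, the ribonuclease at -4.76 ± 1.73 and the kinase Os11g0113700 at -5.45 ± 2.28, and these were not called.

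Adjusted over the list alone, 202 ribosomal genes rose and 11 fell, the meristem, heat shock, WRKY and expansin lists had 1 more member called, and all other lists had the same counts. Of 234 ribosomal protein genes, Os02g0235600 (L11) rose by 1.70 ± 0.10 and Os08g0505300 (L31) by 1.59 ± 0.11, and the median of the list was 0.60, while the median of all genes was 0.02 and went to -0.19 with normexp. Histones had 26 rises and 3 falls of 48 (26 and 9 with normexp), such as H4 (Os02g0684500, 3.47-fold). Heat shock proteins had 57 rises and 24 falls of 115 (48 and 38 with normexp), such as a small heat shock protein (Os02g0758000, 13.2-fold), an Hsp20 gene (Os03g0266300, 9.98-fold) and Hsp70 (Os01g0840100, 7.44-fold). Defence genes had 7 rises and 1 fall of 14, with OsWRKY45 at 2.32 ± 0.21 and OsNPR1 at 1.27 ± 0.10, but 6 and 5 with normexp. WRKY factors had 33 rises and 11 falls of 60 but 21 and 23 with normexp, and disease resistance proteins 88 and 28 of 205 but 46 and 97 with normexp.

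Of 9 clock genes 8 fell and 0 rose, among them OsLHY (-1.47 ± 0.16) and OsGI (-0.96 ± 0.08). Photosynthesis genes fell in 20 of 21 members and rose in 1, with PRK at -1.0 ± 0.07 and PSBQ at -1.19 ± 0.10, but after quantile normalization 4 fell and 1 rose. Light harvesting and photosystem proteins had 37 falls and 5 rises of 44, but 17 and 5 after quantile normalization, and Os01g0720500 fell 8.11-fold. Other genes of like signal fell too, with medians of -0.75 against -0.78 for photosynthesis and -0.70 against -0.81 for light harvesting. Peroxidases had 33 falls and 10 rises of 57, such as peroxidase 12 (Os01g0962700, 7.27-fold lower), and expansins and related proteins 12 falls and 3 rises of 26, such as Os10g0542400 (-2.29 ± 0.08). Purple acid phosphatases had 7 falls and 1 rise of 9, SPX proteins 6 and 0 of 9, glycerophosphodiester phosphodiesterases 5 and 0 of 9, sensing genes 7 and 2 of 14, and scavenging genes 8 and 5 of 15. OsPAP10a stood at -2.19 ± 0.13 and OsSPX1 at -1.66 ± 0.18, the latter turning to 0.41 ± 0.74, not called, with series and slide as terms. These values average both soils, except in Nipponbare 2012, which had LP alone. The mean of the scavenging list changed by -1.87 (SD 0.31, n = 7 series) in LP and 0.17 (SD 0.19, n = 6) in HP, OsSPX1 by -3.00 and -0.019, and OsPAP10a by -3.08 and -1.02.

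Iron genes had 1 rise and 3 falls of 11, the nicotianamine synthase OsNAS3 falling 19.8-fold and the ferritin OsFER2 3.37-fold. Nitrogen genes had 3 rises and 6 falls of 13, with the ammonium transporter OsAMT1;3 at 1.22 ± 0.09 (-0.13 ± 0.60, not called, with series and slide as terms) and the plastid glutamine synthetase OsGS2 at -0.88 ± 0.07 (-0.059, not called, after quantile normalization). Sucrose and starch genes had 1 rise and 5 falls of 7, OsGBSSI rising and OsGBSSII falling. Senescence genes had 3 rises and 1 fall of 8, including the regulator OsNAP (1.15 ± 0.24) and chlorophyll b reductase NYC1 (-1.01 ± 0.08). OsNAP stood at 0.15 with normexp and at -1.57 ± 1.14 with series and slide as terms, and was called in neither. Abscisic acid and jasmonate genes had 4 and 4 of 12, glutathione S-transferases 17 and 19 of 51, and glutaredoxins 7 and 9 of 26. Over all genes 7254 of 23168 rose and 6944 fell, and a list near that share does not stand apart. Among markers of other tissues, meristem and dividing cells had 1 rise (PCNA, 3.53-fold) and 2 falls of 4, and floral organs 2 rises (OsMADS1, OsMADS16) and 2 falls (OsMADS2, OsMADS6) of 6.

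Limma called 14198 of 23168 genes between late and early, 7254 higher and 6944 lower late, or 5144 and 10769 with normexp, and 4649 changed more than 2-fold. Camera called 11 lists at the preset correlation, 5 up and 6 down, and 0 with an estimated correlation, where the smallest adjusted p was 0.327. The median and the mean differ in sign for the meristem and floral organ markers. With series and slide as terms the count was 2775, and of the genes called in the full comparison and tested there 87.2% had the same sign and 1785 the other. Within the 5 slides that hold early and late arrays it was 8004, of which 7401 were also called in the full comparison. Each of these slides sets late arrays of 1 series against early arrays of another, of a different cultivar on 4 slides and of the other soil on 1, so its values mix stage with cultivar or soil. Age, date and weather change together along the season and cannot be told apart here.

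The 4 cultivars of 2016 ask how indica leaves differ from japonica leaves through 1 season. Errors come from the spread between LP and HP series of a cultivar, so the results describe these 4 cultivars and not each subspecies at large. Indica leaves held more transcript of OsMADS14, 3.25-fold over the season (1.70 ± 0.06, SE, n = 8 series), and more of the clock gene OsPRR37 (0.82 ± 0.07). The phosphate transporter OsPT8 was 10.7-fold lower. Of the disease resistance list 110 of 208 members were lower in indica and 61 higher, but 90 and 82 after quantile normalization and 69 and 80 with normexp.

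By day, in values chosen after they were seen, OsMADS14 differed by 1.96 at 42 DAT, 3.57 at 49 DAT, 4.30 at 56 DAT and 3.42 at 62 DAT, all higher in indica (log2, 4 series against 4, exact p = 0.0286 each, the smallest that 8 series allow, adjusted p = 0.0408). This test takes the LP and HP series of a cultivar as separate units, and with 2 cultivars against 2 no exact p under 0.333 is possible. The metallothionein Os05g0202800 did not pass at any day (smallest adjusted exact p = 0.238).

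**Figure D4:**
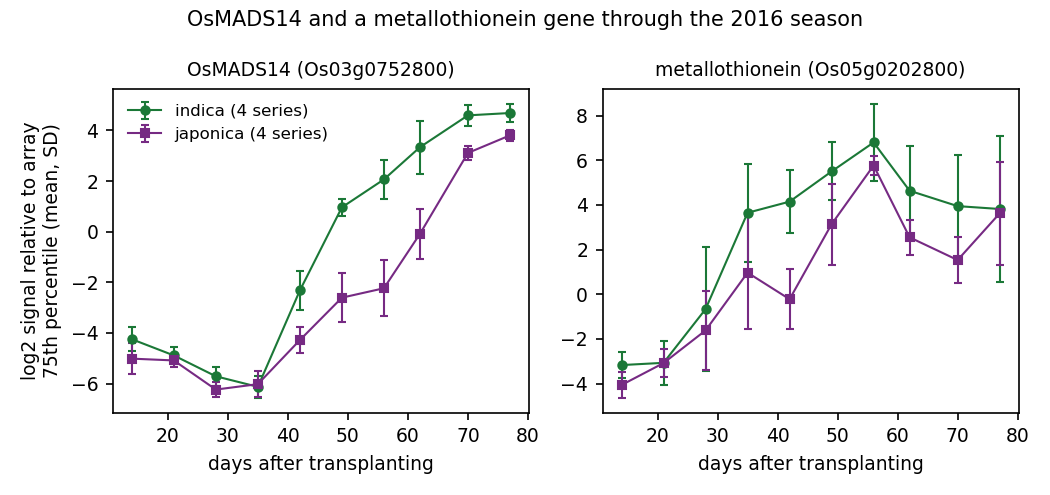
OsMADS14 and the metallothionein Os05g0202800 (log2 signal against the array's 75th percentile, mean and SD of 4 series) by days after transplanting in indica and japonica leaves of 2016. OsMADS14 in indica lies 4.30 above japonica at 56 DAT and 0.88 above it at 77 DAT.

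Some genes were near background in 1 subspecies. Beta-amyrin synthase (Os02g0140400), of triterpene synthesis, was at least 218-fold higher in indica, a prenyltransferase-domain gene (Os01g0684800) at least 57.6-fold and a transposon protein (Os03g0625100) at least 33.4-fold. An F-box gene (Os01g0380800, 9.60 ± 0.08), a glucosyltransferase (Os10g0122000, 8.81 ± 0.11), a disease resistance response gene (Os11g0214400, 8.76 ± 0.13), a haem peroxidase (Os12g0448900, 8.31 ± 0.09) and a beta-glucosidase aggregating factor (Os12g0199000, 7.64 ± 0.05) were also higher, and were well above background on 1, 1, 3, 22 and 40 of 40 japonica arrays, so that all but the last are differences from a signal often near background. Among the largest falls, 7 lay between -11.11 and -10.48, namely a CBS domain gene (Os04g0136700), a protein phosphatase 2C (Os01g0164600), a cytochrome P450 (Os11g0465200), an RNA-binding protein (Os06g0170500), a copine (Os01g0960500), an ankyrin repeat gene (Os01g0942900) and the resistance gene Os11g0588600, each well above background on 1 to 7 of 40 indica arrays and on 40 of 40 japonica arrays, so their size depends on values near background. For the resistance gene Os06g0287700, also called lower, these were 0 and 40. No difference or bound is given for it, since another of its 3 probes was above background in indica. Beyond 16-fold, 787 genes were lower and 112 higher in indica, of which 687 were well above background on fewer than 20 of the 40 arrays of the lower subspecies, and the probes follow the japonica sequence.

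Flowering genes were higher in 9 of 12 and lower in 1 (OsMADS18, -0.70 ± 0.06), with DTH8 at 1.43 ± 0.12. Clock genes were higher in 8 of 9, but 4 after quantile normalization. Sensing genes were higher in 8 and lower in 1 of 13 (OsIPS1 1.51 ± 0.17), scavenging genes higher in 5 and lower in 6 of 15, SPX proteins 4 and 1 of 8, purple acid phosphatases 2 and 6 of 9, and glycerophosphodiester phosphodiesterases 4 and 3 of 9. Photosynthesis genes were higher in 17 and lower in 1 of 21 (PRK, -0.43 ± 0.05), but 3 and 3 after quantile normalization, and light harvesting proteins in 32 and 5 of 44, but 9 and 7. Other genes of like signal were higher in indica too, with medians of 0.37 against 0.37 for photosynthesis and 0.30 against 0.40 for light harvesting. Defence genes were higher in 4 and lower in 9 of 14, with the phytoalexin genes CYP76M7 at -3.75 ± 0.07 and OsMAS at -2.63 ± 0.13 (-0.14, not called, with normexp) and OsKSL10 at 4.52 ± 0.14. Expansins were higher in 15 and lower in 4 of 25 (OsEXPA13 3.25 ± 0.07), peroxidases in 29 and 12 of 58, heat shock proteins in 45 and 31 of 116, and WRKY factors in 25 and 16 of 59. Over all genes 9251 of 23424 were higher and 7566 lower in indica, and a list near that share, here or below, does not stand apart.

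Ribosomal proteins were higher in 42 and lower in 90 of 234, S15a (Os02g0255200) being at least 49.7-fold lower in signal. The probes follow the japonica sequence, so sequence divergence or absence of that gene stays open. Histones had 13 higher and 18 lower of 48, glutathione S-transferases 16 and 20 of 51, and glutaredoxins 11 and 8 of 27. Iron genes had 3 and 3 of 11, with OsNAS1 at 3.85 ± 0.20 and OsNAS2 at -2.50 ± 0.28, nitrogen genes 5 and 3 of 13, and sucrose and starch genes 2 and 3 of 7. Senescence genes had 3 and 2 of 8, abscisic acid and jasmonate genes 3 and 4 of 12, meristem markers 0 and 2 of 4 (OSH1, PCNA), and floral organ markers 4 and 1 of 6. Adjusted over the list alone, 39 and 85 ribosomal genes passed, and the other lists differed by at most 1 member. The median and the mean differ in sign for scavenging genes, WRKY factors, histones and glutaredoxins.

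Limma called 16817 of 23424 genes between subspecies, 9251 higher and 7566 lower in indica, or 11223 and 5704 with normexp and 10710 and 6692 after quantile normalization. The spread among cultivars of a subspecies does not enter these p-values, so the counts hold for the cultivars sampled. Camera called photosynthesis, light harvesting and disease resistance at the preset correlation and 0 lists with an estimated one (adjusted p = 0.816, 0.811 and 0.811). Within LP and within HP, each of 1 scan batch, the counts were 4800 (2188 higher and 2612 lower) and 4915 (2190 and 2725), so that more genes were lower than higher there. No slide held both subspecies, so slide and subspecies cannot be told apart within slides.

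A calmodulin-like gene (Os12g0228800, 7.74 ± 0.25, SE, n = 2 series each), an ent-kaurene oxidase of gibberellin synthesis (Os06g0569900, 6.87 ± 0.19) and a BURP domain gene (Os02g0288600, at least 19.8-fold) were higher in Koshihikari than in Nipponbare leaves. The first was well above background on 9 and the second on 1 of 20 Nipponbare arrays. A protein kinase (Os02g0615800) was at least 1316-fold lower, a jacalin-related lectin (Os04g0330200) stood at -11.00 ± 0.16 and IN2-2 protein (Os04g0338100) at -13.12 ± 0.23, with signal well above background on 1 and 3 of 20 Koshihikari arrays, so the size of both depends on values near background. Limma called 1374 of 23251 genes, 441 higher and 933 lower (634 and 775 after quantile normalization), 679 of them more than 2-fold, in a design that recovered 1 of 67 simulated 2-fold changes. The count was 719 without Nipponbare LP, 927 without Nipponbare HP, 610 without Koshihikari LP and 782 without Koshihikari HP.

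Takanari exceeded IR64 in a tau class glutathione S-transferase (Os10g0529800, 10.56 ± 0.12), a barwin-related gene (Os04g0364800, 9.75 ± 0.24) and a leucine-rich repeat gene (Os06g0274300, 9.57 ± 0.19), which were well above background on 7, 1 and 1 of 20 IR64 arrays. IN2-2 protein (Os04g0338100, -11.50 ± 0.22), methyl chloride transferase (Os03g0843800, -11.22 ± 0.14) and an ATPase-like gene (Os12g0292900, -10.43 ± 0.08) were lower in Takanari, and were well above background on 3, 6 and 1 of 20 Takanari arrays. The size of these 6 differences depends on values near background. Limma called 5978 of 22386 genes, 3226 higher and 2752 lower (2859 and 3256 after quantile normalization), and 3730 without Takanari LP, 4024 without Takanari HP, 3597 without IR64 LP and 3754 without IR64 HP. That more genes were called here than between the japonica cultivars was not tested as a difference.

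Nipponbare leaves of 2014, 2015 and 2016 differed past the threshold in 2 genes of 22841, a Myb gene (Os02g0114800, year means 5.63 apart on the log2 scale, adjusted p = 0.0268) and Os08g0489300 (4.22 apart, adjusted p = 0.0479). The count was 944 with normexp and 165 with the 75% filter, in a design that recovered 0 of 66 simulated 4-fold changes. At an unadjusted p under 0.05 limma had 3768 genes. Without LP 2014 the count was 1478, without HP 2014 it was 1286, and without any 1 of the other 4 series it was 0. Year and array batch cannot be told apart, since years lay on different slides.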

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

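The tests on scan batch, on older HP plants, on scaling, on bright probes, on single probes and within slides for growth stage, those on microRNA probes and on the early window, and splits by year or cultivar were chosen only after the result was seen. With the signs of the 6 pairs flipped in all 32 ways, only 1 way, the real one, gave as many genes for soil over all rounds (1335, highest other 32), for soil in the early window (2150, highest other 1), for soil by stage (198, highest other 1) and for the first 3 sampling rounds (135, 201 and 212, highest other 0, 1 and 0). Only 1 of 64 flips gave as many for growth stage (14198, highest other 6). This argues against chance for each count taken alone, where the units are taken as independent. A share of 1 in 32 is the smallest that 6 pairs allow. The soil counts overlap and were not adjusted for their number, and the early window was chosen after the data were seen. However, 4 units share the year 2016 (and, for soil, its scan batches). Their soil differences correlated across genes at 0.33 to 0.64, genes not being independent replicates. Nipponbare pairs of different years correlated at 0.18 (2014 with 2015), 0.12 (2015 with 2016) and 0.02 (2014 with 2016). Across years and cultivars the correlation reached 0.46 (Nipponbare 2015 with Koshihikari 2016). With whole years flipped, the 4 flips for soil (highest other 32 over all rounds and 0 for the other counts) and the 8 for growth stage (highest other 6) are too few for a share under 0.05. For subspecies the 3 splits that keep both series of a cultivar together are too few as well (11520 genes in a fit without cultivar terms, highest other 28).

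Genes for phosphate scavenging, lipid remodelling and uptake were higher in LP than in HP leaves early in the season, and LP minus HP changed between early and late in 198 genes. A difference between scan batches was argued against by the pair scanned in 1 batch, where the list was higher in LP by 2.14 (log2, SD 0.16, n = 3 rounds). The early LP arrays of that pair lay on slide 8 and the early HP arrays on slides 10 and 11, so a difference between slides stays open. HP plants being further along in age stays open: the list fell from early to late in LP, by a mean of -1.87 (SD 0.31, 7 of 7 series), and not in HP, at 0.17 (SD 0.19, n = 6), but this restates that the difference was lost and does not tell the explanations apart. The pattern may reflect phosphate supply, as a hypothesis that leaf phosphate content or phosphate added to the LP field would test, neither of which was analysed here, and other differences between the fields stay open as well.

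In the values used, late leaves had more transcript of ribosomal proteins and less of nuclear photosynthesis genes. For the ribosomal part scaling was argued against, with a median rise of 0.58 (SD 0.19, n = 7 cultivar-years) under normexp, while the slide stays open, with a rise of 0.62 (SD 0.40, n = 5 slides) within slides once the season-long difference of the 2 series on each slide was subtracted. For the photosynthesis part the slide was argued against by the same measure, at -0.69 (SD 0.22). Scaling stays open there, with a median of -0.021 (SD 0.039, n = 7) after quantile normalization but -0.76 (SD 0.17, n = 7) with normexp, as does a fall of all bright probes, since the list lay -0.035 (SD 0.033, n = 7) from other genes of like signal, while light harvesting and photosystem proteins lay -0.11 (SD 0.034, below in 7 of 7) from theirs. Plant age, weather and leaf rank are open for both parts and were not tested.

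Some genes described as disease resistance proteins were far lower in indica. A mismatch in a single probe was argued against for the 14 list genes with several probes and a fall beyond 4-fold. Of these, 92.9% also fell at every other probe, though by less (median -2.57 against -4.11). Among all genes with several probes and such a fall the share was 91.5% (270 of 295), so it is not particular to this list. Such a mismatch stays open for the 38 list genes with a like fall and no other probe to compare. The lowest mean of 10 japonica slides lay 0.43 above the highest of 10 indica slides. No slide held both subspecies, so this regroups the same arrays, and a difference between indica and japonica slides stays open. Sequence divergence across all probes of a gene, or absence of the gene from indica genomes, could give the same picture and stays open, as does lower expression. The direction of the list depends on scaling, with 110 lower, 61 higher and a median of -0.26 in the values used, but 69 lower, 80 higher and a median of 0.088 with normexp (-0.025 after quantile normalization).

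Units far from the others were looked for in 195 groups of 6 or 7 units, and 14 groups held one, where chance gives about 1 in 20. In the soil comparison OsEXPA2 (Os01g0823100) was 0.13 in Nipponbare 2016 against 0.56 to 0.79 in the other pairs, and OsSPS1 (Os01g0919400) 1.5 in Nipponbare 2014 against 0.36 to 0.78. The nitrogen, glutathione S-transferase and glutaredoxin lists stood at 0.44, 0.29 and 0.25 in Nipponbare 2014, above all other pairs. For growth stage, OsFER2 (Os12g0106000) was -2.55 in Takanari. Nipponbare 2012 had an LP series alone, sampled from 21 to 84 DAT, and was read with another scanner. It stood apart with OsPAP10a (Os01g0776600) at -2.94, H4 (Os02g0684500) at 2.70, a glutathione S-transferase (Os10g0531400) at 3.90 and the clock list at -1.93. OsPAP10a fell more in LP than in HP series, and soil, days and scanner cannot be told apart for this unit. The sucrose and starch list was 0.51 in IR64 and the light harvesting list -0.90 in Nipponbare 2016. For soil by stage, a purple acid phosphatase (Os03g0238600) was -2.30 in Nipponbare 2016 and the abscisic acid and jasmonate list -0.85 in Nipponbare 2015.

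The array also carries probes for microRNA precursors without a locus ID, which no comparison of the report uses. Of 211 tested, limma called 10 in the early window, all higher in LP (27 at an unadjusted p under 0.05), and 9 of these were for microRNA399, which is known to rise when phosphate is short. LP minus HP was 2.24, 5.63 and 4.31 for 3 probes of miR399j, 2.44 for miR399c, 2.76, 2.08 and 2.79 for 3 probes of miR399d, 1.57 and 1.08 for 2 probes of miR399i, and 1.04 for miR156g (log2, n = 6 pairs, all 6 higher except 5 of 6 for the miR399i probe at 1.57). Another filter, over all probes without a locus ID, called 6 of 231, all higher. In the late window 0 of 211 were called (3 at an unadjusted p under 0.05).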

How the results depend on the processing

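Of these alternatives, windows, single soils, slide terms, the 2015 pair alone and all alternatives of the early window were chosen after seeing the data. Of values of named genes under alternatives, 539 of 793 for soil, 1311 of 1346 for stage, 873 of 896 for subspecies, 54 of 54 for each cultivar comparison and 154 of 176 for soil by stage kept their direction and their side of the threshold. Over all 323 genes the rule allows, named or not, 5424 of 6232 values did, 657 lost their call, 102 gained one and 49 reversed. The cause was not tested for the changes below unless given.

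The soil count of 1335 was 390 with no filter, 9366 with arrays as units, 6031 with the slide as a random block, 2514 in the 4 pairs of 2016, and 0 in the 3 Nipponbare pairs (1453 at an unadjusted p under 0.05), where fewer units were tested, and within the 2015 pair (3014), with its 9 rounds as units. Early arrays alone gave 2150, and middle and late arrays 0 and 0 (3606 and 3381). Leaving out 1 pair gave 107 (without IR64), 138 (Koshihikari), 172 (Takanari), 514 (Nipponbare 2015), 571 (Nipponbare 2016) or 2336 (Nipponbare 2014). With normexp 1023 were higher and 564 lower, against 466 and 869. RCCR1 went to 0.026 with normexp and OsEXPA2 to -0.0046 in early arrays alone. In late arrays alone Os02g0325600 was -0.091, OsSPX1 -0.067, Os04g0517500 -0.035, OsSQD2.1 -0.038, OsSPX3 -0.17, OsSPX-MFS1 0.14, OsMGD2 -0.016, Os04g0394100 -0.39 and OsSPX2 -0.044. The early count of 2150 was 33 in the 3 Nipponbare pairs, 566 in the 4 pairs of 2016, 3 in the 2015 pair (1278 at an unadjusted p under 0.05), and 496 (without Koshihikari) to 1480 (without Nipponbare 2014) with 1 pair left out.

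Growth stage went from 14198 to 2775 with series and slide as terms, where OsSPX1 was 0.41, OsNAP -1.57, OsAMT1;3 -0.13 and SalT 0.15, and to 8004 within 5 slides, where stage is mixed with cultivar or soil. Leaving out 1 cultivar-year gave 12700 to 14076, and normexp gave 5144 higher and 10769 lower. Subspecies gave 4800 in LP and 4915 in HP alone, with 2 series against 2, and 14698 to 16098 with 1 series left out. With normexp 11223 were higher and 5704 lower. Koshihikari against Nipponbare gave 610 to 927 with 1 series left out, and 634 higher and 775 lower after quantile normalization. Takanari against IR64 gave 3597 to 4024, and 2859 higher and 3256 lower after quantile normalization. Year gave 944 with normexp, 1 with the deposited table, 1 with the mean of probes, 0 with no filter, 165 with the 75% filter and 0 to 1478 with 1 series left out. Soil by stage gave 92 (without IR64) to 167, and soil by subspecies 0 to 0.

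Lists called numbered 1 for soil, 0 for stage and 0 for subspecies with an estimated correlation. With fry, which compares no list with other genes, they numbered 19 for stage and 21 for subspecies. For subspecies 1 list, ribosomal proteins, was called after quantile normalization and with normexp, and 0 of the 3 lists called with the values used. After quantile normalization the photosynthesis and light harvesting lists had medians of 0.030 and 0.043 and turned from up to down in camera (adjusted p = 0.764 and 0.935). The phosphate score of Nipponbare 2014 was 0.31 with normexp (adjusted exact p = 0.164) and 0.52 after quantile normalization (0.105). The first round gave 213 genes with normexp, and rounds 4 to 10 together, 9 in the values used, gave 30 with normexp and 16 after quantile normalization. The signal over background limits genes such as OsIPS1, OsMGD2 and OsSPX3, which lay near background in most early HP arrays.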

Other observations

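The probes for microRNA precursors, in tests chosen after the data were seen, also changed with the season. Of 205 tested, limma called 120 between late and early leaves, 13 higher and 107 lower late (122 at an unadjusted p under 0.05). All 33 probes of miR169 (15 precursors), a family that targets NF-YA transcription factors, fell, by a median of -3.09 (log2, range -6.96 to -0.82, n = 7 cultivar-years). All 13 tested probes of miR399 (8 precursors) fell, by a median of -1.19. Probes of miR399 were higher in LP early, and the soils were not taken apart here. For miR399 a change with age and the loss of that difference therefore cannot be told apart. The largest rises were at the probes of miR528 (2.59 and 2.36), miR398b (2.14) and miR530 (2.01 and 1.92).

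Beyond 16-fold, 101 genes were lower and 18 higher in Koshihikari than in Nipponbare, and 153 were lower and 253 higher in Takanari than in IR64. Of these, 101 and 325 were well above background on fewer than 10 of the 20 arrays of the lower cultivar, so their size depends on values near background.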
